A study of Mus musculus with 8 samples.

How the data were processed

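Gene expression was measured by RNA sequencing in 8 libraries of mouse peritoneal macrophages. The 4 groups of 2 libraries combined genotype, floxed control (called WT here, as in the labels) or macrophage MED1 knockout (KO), with treatment, none or lipopolysaccharide (LPS) at 50 ng/mL for 6 h. The mice were 8 weeks old and of the C57BL/6J strain. Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned with TopHat2 2.0.14, and expression was estimated with Cufflinks 2.2.1 on the mm9 genome. The gene annotation, the strandedness, the pairing of reads and the Cre driver of the knockout are not given in the sources used here. The labels mark the libraries of each group A and B without saying what the letters stand for or whether each library came from a separate animal, so an adjusted p here measures a change against the spread between these libraries.

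The deposited values are RPKM, reads per kilobase of transcript scaled to the mapped reads of a library, as the authors computed them, in 1 table of 24192 lines. These lines hold 23735 loci, because 457 lines repeat a locus under another symbol with the same values, and each locus was used once. In the table, 340 loci carry several symbols and 26 carry a calendar date in place of a symbol; the latter were tested but not named. All sample columns of the table were used.

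No count of reads is given, so depth was estimated from the steps between low values. The most common ratio between libraries over 1420 loci with low values gave the depth of each library relative to the deepest. With libraries scaled by these ratios, 93.9% of the loci had only whole multiples of 1 step among their nonzero values. The tolerance was 0.1 read plus 0.02 per read. The step was fitted per locus, as its smallest value or a whole fraction of it. The depth of the deepest, KO untreated A, was set at 14.6 M mapped reads (quartiles 13.8 and 14.9) from 373 genes with 1 annotated transcript in GENCODE vM1 on the same genome build. The other libraries then held 7.1 to 11.4 M, and 1 read on a transcript of 1 kb stood for 0.0687 to 0.141 RPKM. Gene positions were taken from the same annotation, matched by symbol.

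Loci with at least 1 RPKM in at least 2 libraries were kept, which left 11272. Values were analysed as log2(RPKM + 1), with the scaling as deposited, in R 4.3.3 with limma 3.58.1. One mean per group was fitted over the 8 libraries, with moderated variances that follow a trend with expression. The 6 contrasts were LPS in WT, LPS in KO, MED1 loss without LPS, MED1 loss with LPS, MED1 loss averaged over treatments, and the interaction, which is the LPS response in KO minus that in WT. Tests were two-sided, and a locus was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values in the text come from limma and the Benjamini-Hochberg method unless another test is named. Log2 changes carry the standard error (SE) of that fit. Figures and depth estimates were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

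The contrasts, the filter, 31 gene lists and the rule for naming genes were chosen before the data were examined. Med1 was named first. For each contrast the rule took up to 12 called genes with the largest rise and up to 12 with the largest fall, with a mean of at least 5 RPKM in the higher group and no overlap between the libraries compared. The overlap condition did not apply to the interaction. Predicted, unnamed and small RNA genes were skipped. Where fewer than 3 genes qualified in a direction, the 3 with the smallest p were named as not passing. Up to 4 members of each list with the largest change, and 14 genes of macrophage activation, were named whether or not they passed. Some genes that the rule took are left out of the text. The microRNA genes in the text fall outside this rule and were named after their values were seen.

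Each list was tested in each contrast with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. A list is said to have risen or fallen, or to be called, where this test passed. Camera sets the changes of a list against those of all other loci and does not test whether the list itself changed. A called list can thus have a median near no change or of the opposite sign. Camera was repeated with the correlation estimated per list, and fry, which asks whether the genes of a list move on balance one way, was run beside it. Of the 31 lists, 30 had members above the filter. Members were counted by their own test over all loci and also adjusted over the list alone. An overlap of calls was set against n1 × n2 / N for independent lists.

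Whether the letters pair libraries across groups was checked before the fits were compared. The deviations of libraries from their group means correlated positively by letter in each of the 6 pairs of groups, with r from 0.20 to 0.41 across loci, and the second principal component (12.9% of the variance) separated A from B. The main fit, which gave the values in the text unless the block is named, leaves the letters out. In a second fit, with the letter as a block, the letters were therefore treated as pairing. This pairing comes from the data and not from the labels, and with 2 letters it amounts to 1 shared difference. Values from a fit with the letter as a block are given beside a result where they change its call or move a count by over 1.5 times.

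Other ways of processing were tried, namely pseudocounts of 0.1 and 0.5, no filter, a filter at 5 RPKM, median-ratio scaling, quantile normalization, scaling to the library sum, the letter as a block, the compared libraries alone, no variance trend, robust variances, library weights, an additive model and each library left out in turn. Leaving out 1 library left its group with a single library, which was assumed to vary like the others. Small RNA loci left out, and a B cell or a mast cell marker score as a covariate, were added after the data were seen. For lists, only median-ratio scaling, the block, the estimated correlation and fry were chosen beforehand, and the rest were run on them afterwards. The method was tested on simulated data in which 200 of the 11272 loci were changed in 1 contrast, in 10 runs. It recovered 13.2% of changes of log2 1, 75.6% of log2 2 and 94.8% of log2 3, with 4.9% false calls. Camera found a shifted list in 10 of 10 runs and an unshifted list in 0. The simulated loci varied independently, without correlation between genes or a difference between letters, and only loci with a mean log2 above 3 were changed. These rates therefore do not measure false calls, of loci or of lists, in data with such structure. Splicing and transcript isoforms were not analysed here, because the table holds 1 value per locus.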

Results

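Peritoneal macrophages labelled as MED1 knockout were compared with floxed controls, each without treatment and after 6 h of LPS. MED1 is a subunit of the Mediator complex, which links transcription factors to RNA polymerase, and LPS is the bacterial cell wall component sensed by TLR4. Each of the 4 groups had 2 libraries, A and B. The libraries held an estimated 7.1 to 14.6 M mapped reads and 10192 to 11027 loci at 1 RPKM or more. The 10 most abundant loci took 14.2% to 23.9% of the RPKM sum. Within groups, the A and B libraries correlated at r = 0.966 in WT, 0.949 in WT with LPS, 0.93 in KO and 0.966 in KO with LPS, across loci, which are not independent. The first principal component (62.7% of the variance) separated LPS-treated from untreated libraries.

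Med1 itself (locus XLOC_003883, mm9 chromosome 11, 98013468 to 98054607, minus strand) did not pass as lower in KO, although its value lay lower in KO in 4 of 4 letter pairs. Its values were 21.7 and 24.8 RPKM in WT, 24.7 and 21.6 in WT with LPS, 17.6 and 23.4 in KO, and 24.4 and 20.3 in KO with LPS (libraries A and B). The KO minus WT difference averaged over treatments was -0.12 on the log2 scale (SE 0.15, 95% interval -0.47 to 0.24, adjusted p = 0.999). Med1 did not respond to LPS detectably either, with log2 changes of 0.00 in WT (adjusted p = 0.994) and 0.12 in KO (adjusted p = 0.718). The value covers the whole locus, and the exons deleted in the knockout are not given in the sources used here, so it does not measure loss of a working transcript. KO below means libraries labelled MED1 knockout.

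**Figure D1:**
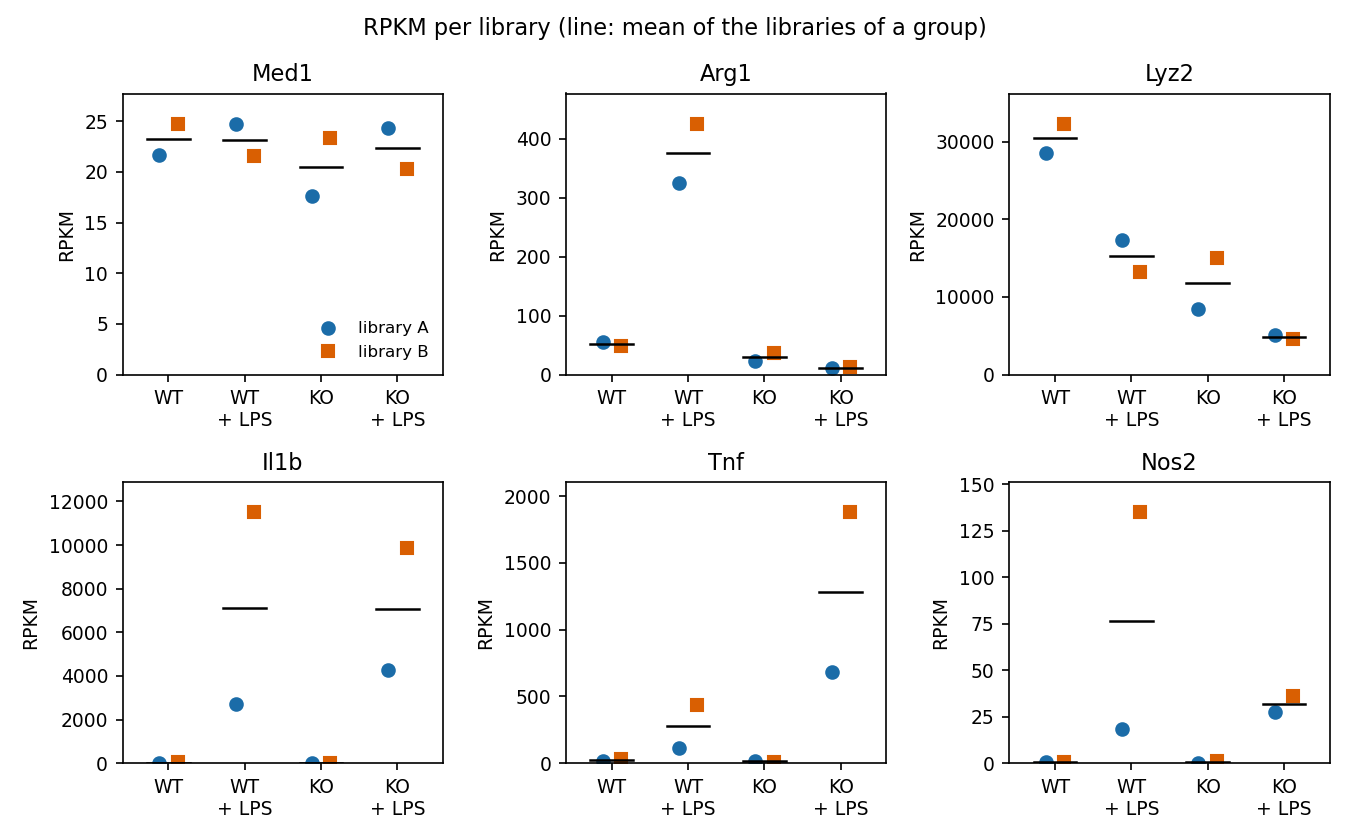
RPKM per library (y axis, linear from 0) of Med1, Arg1, Lyz2, Il1b, Tnf and Nos2 in the 4 groups (x axis), with circles for libraries A, squares for libraries B and a line at the group mean. Med1 lies between 17.6 and 24.8 RPKM in all 8 libraries, while Arg1 reaches 325 and 425 RPKM in WT with LPS and 11.5 and 12.4 RPKM in KO with LPS.

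The LPS response of control macrophages came first. In WT, LPS raised transcripts for secreted inflammatory mediators. Il1b, which encodes the fever-inducing cytokine interleukin-1 beta (chromosome 2, 129190306 to 129196875), went from 29.2 ± 22.2 to 7102 ± 6235 RPKM (SD, n = 2), a log2 change of 7.76 (SE 0.81, adjusted p = 0.0099). Il6 rose by log2 7.34 (SE 1.37, adjusted p = 0.0281) and the granulocyte growth factor Csf3 by 7.10. Il1a rose by 6.25, Csf2 by 5.59 and Tnf by 3.35 (adjusted p = 0.037). Of 18 cytokines measured, 10 rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 change of 3.24 (camera adjusted p = 1.3e-12, and adjusted p = 0.27 with an estimated correlation). Of 18 chemokines, 7 rose, among them the T cell attractant Ccl5 (6.52) and the neutrophil attractants Cxcl3 (6.31) and Cxcl1 (5.36), and 0 fell (12 and 0 adjusted over the list alone; median 3.33, camera adjusted p = 1.6e-13, and adjusted p = 0.24 with an estimated correlation). The interferon-induced chemokine Cxcl10 had a log2 change of 5.94 (adjusted p = 0.0651; 0.00952 with the letter as a block).

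Interferon-response genes rose together: 15 of 30 passed upward and 0 downward (25 and 0 adjusted over the list alone), with a median of 1.88 (camera adjusted p = 2.6e-22, and adjusted p = 0.27 with an estimated correlation). Among them were the ubiquitin-like Isg15 (3.46) and the RNA-binding Ifit1 (3.09). Ifnb1, the interferon beta gene, lay below the filter in all groups. Inhibitors and components of the NF-kB pathway rose as a list, with 11 of 23 passing (18 adjusted over the list alone; median 1.78, camera adjusted p = 6.8e-20, and adjusted p = 0.24 with an estimated correlation). Examples are the cytokine signalling inhibitors Socs1 (4.85) and Socs3 (3.43), the adaptor Traf1 (3.24) and the co-stimulatory receptor Cd40 (2.68). Of 16 microbicidal and prostaglandin genes, 8 rose and 0 fell (10 and 1 adjusted over the list alone; median 2.22, camera adjusted p = 7.3e-08, and adjusted p = 0.24 with an estimated correlation). These included the iron-sequestering lipocalin Lcn2 (6.23), the prostaglandin synthase Ptgs2 (5.82), the nitric oxide synthase Nos2 (5.03, adjusted p = 0.0208) and the arginine transporter Slc7a2 (4.93). The uridine phosphorylase Upp1 (5.85, adjusted p = 0.000298), the matrix metalloproteinase Mmp3 (5.69) and the activin subunit Inhba (5.46) also rose. In the list of LPS sensing genes, 4 of 22 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.22, camera adjusted p = 0.0018, and adjusted p = 0.27 with an estimated correlation). They included the LPS co-receptor Cd14 (2.75), the receptor Tlr4 (1.13) and the adaptor Myd88 (1.11).

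Genes of lipid handling and mitochondrial respiration fell in WT. All 18 measured PPAR targets and fatty acid oxidation genes had lower values and 3 fell (13 adjusted over the list alone), with a median of -1.16 and of -0.73 without WT LPS B (camera adjusted p = 2e-05, and adjusted p = 0.65 with an estimated correlation). The fatty acid carriers Fabp5 (-3.37) and Fabp4 (-2.30) were among them, while the fatty acid transporter Cd36 had a change of -1.52 (adjusted p = 0.101; 0.0335 with the letter as a block). Of 75 oxidative phosphorylation genes, 74 had lower values and 1 fell (15 adjusted over the list alone; median -0.71, camera adjusted p = 1.6e-08, and adjusted p = 0.84 with an estimated correlation). Ribosomal protein genes were lower as a list, although 0 of 76 passed singly in limma (median -0.38, camera adjusted p = 0.0074, and adjusted p = 0.99 with an estimated correlation), a call that ended with median-ratio scaling (0.2) and without WT LPS A (0.17). Among the largest falls were those of the endoglycosidase Engase (-4.11), the transmembrane glycoprotein Gpnmb (-3.58), the proton pump subunit Atp6v0d2 (-3.40), the diacylglycerol lipase Daglb (-3.37), the thiosulfate sulfurtransferase Tst (-3.30), the efferocytosis ligand Gas6 (-3.16) and the cholesterol ester hydrolase Nceh1 (-3.13). Slc9a3r2 (-3.61), Ptplad2 (-3.50) and Tmem37 (-3.05) fell as well.

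Few alternative activation genes passed in WT, and none of them fell. Arg1, the enzyme that splits arginine into ornithine and urea, rose 7.20 times, from 52.1 ± 5.58 to 375 ± 70.9 RPKM (SD, n = 2; log2 2.82, adjusted p = 0.00683), and the interleukin-4 receptor Il4ra rose by 1.78. The other markers always named gave changes of -1.28 for Retnla (adjusted p = 0.247) and -0.07 for the mannose receptor Mrc1 (adjusted p = 0.942). The list had 2 of 17 members up and 0 down (3 and 0 adjusted over the list alone; median 0.08, camera adjusted p = 0.0087, and adjusted p = 0.24 with an estimated correlation). That call ended with median-ratio scaling (0.098) and without WT LPS B (0.11), and the median was -0.03 without WT untreated A. The cholesterol exporter Abca1 rose by 1.56 (adjusted p = 0.0285), while 11 of 14 LXR target and efflux genes had lower values (median -0.32, camera adjusted p = 0.83). Arg1 kept its direction without any 1 library, but its adjusted p was 0.0664 without WT untreated A and 0.0523 without WT LPS B.

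In all, 357 loci rose and 354 fell with LPS in WT, of 11272 tested, and 3300 had an unadjusted p under 0.05 where chance gives 564. The median of all loci was -0.25 in WT and -0.28 in KO, and median-ratio scaling shifted these medians by 0.23 and 0.25 (quantile normalization by 0.21 and 0.22). With the letter as a block 644 rose and 1174 fell. The number of calls depended on single libraries: it was 9 without WT untreated A, 84 without WT untreated B, 33 without WT LPS B, 2242 without WT LPS A, and 379 without either KO LPS library. Of 50 named genes called here, 49 lost their call without WT untreated A, 39 without WT untreated B, 46 without WT LPS B, 9 without either KO LPS library, 4 without either KO untreated library and 1 without WT LPS A. Upp1 alone kept it throughout.

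In KO macrophages LPS raised many of the same mediators. Il1b went from 13.2 ± 4.80 to 7058 ± 3961 RPKM (SD, n = 2; log2 8.88, adjusted p = 0.00539) and Il6 by log2 8.65 (adjusted p = 0.02). Tnf (chromosome 17, 35336326 to 35338952) went from 15.2 ± 4.16 to 1281 ± 849 RPKM (log2 6.15, adjusted p = 0.00933). Csf3 rose by 8.34, Il1a by 7.49 and Csf2 by 7.10. Of 18 cytokines, 11 rose and 0 fell (16 and 0 adjusted over the list alone; median 4.15, camera adjusted p = 6.6e-19, and adjusted p = 0.23 with an estimated correlation). Of 18 chemokines, 8 rose, led by Cxcl3 (8.34), Cxcl1 (7.73), Cxcl2 (7.18) and Ccl5 (6.21), and 1, Ccl6, fell (-1.61); adjusted over the list alone, 12 rose and 1 fell (median 4.43, camera adjusted p = 3.9e-13, and adjusted p = 0.23 with an estimated correlation). Cxcl10 had a change of 4.72 (adjusted p = 0.105; 0.0213 with the letter as a block).

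Of 30 interferon-response genes in KO, 17 rose and 0 fell (25 and 0 adjusted over the list alone; median 1.86, camera adjusted p = 4.1e-26, and adjusted p = 0.25 with an estimated correlation), including Isg15 (3.96), Ifit1 (3.41) and the antiviral enzyme Rsad2 (3.34). Of 23 NF-kB regulators, 16 rose and 0 fell (22 and 0 adjusted over the list alone; median 2.04, camera adjusted p = 6.6e-25, and adjusted p = 0.23 with an estimated correlation), among them Socs1 (3.39), Traf1 (3.32) and Cd40 (3.28). Of 16 microbicidal and prostaglandin genes, 9 rose and 0 fell (10 and 2 adjusted over the list alone; median 2.15, camera adjusted p = 2e-09, and adjusted p = 0.23 with an estimated correlation). Ptgs2 rose by 7.74, Slc7a2 by 5.30, the itaconate-producing enzyme Irg1 by 5.11, Lcn2 by 4.71 and Nos2 by 4.40 (adjusted p = 0.0267), and Mmp3, outside the lists, by 7.32. Genes of the NRF2 antioxidant response rose as a list, 4 of 12 singly (7 adjusted over the list alone; median 1.24, camera adjusted p = 2.5e-08, and adjusted p = 0.44 with an estimated correlation). They were the cystine transporter Slc7a11 (3.81), the thioredoxin reductase Txnrd1 (2.12), the sulfiredoxin Srxn1 (2.05) and the autophagy receptor Sqstm1 (2.01), and the list median was 0.81 without KO untreated B. Of 22 LPS sensing genes, 4 rose, Cd14 by 2.42, and 0 fell (5 and 0 adjusted over the list alone; median 0.10, and 0.20 without KO LPS B; camera adjusted p = 0.0013, and adjusted p = 0.31 with an estimated correlation).

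Among genes that fell in KO were Engase (-4.48), the anticoagulant receptor Thbd (-3.42), the G protein regulator Rgs2 (-3.39), the matrix protein Tgfbi (-3.34), Tifab (-3.20), the RNA sensor Tlr8 (-3.07) and the retinal reductase Dhrs3 (-3.01). Ptplad2 (-3.89), Tmem37 (-3.83), Slc9a3r2 (-3.21) and Daglb (-3.11) fell here as in WT. Of 18 PPAR targets and fatty acid oxidation genes, all had lower values and 5 fell (9 adjusted over the list alone), including Angptl4 (-2.87) and the rate-limiting carnitine transferase Cpt1a (-2.16; list median -0.86, camera adjusted p = 6.4e-05, and adjusted p = 0.65 with an estimated correlation). Of 75 oxidative phosphorylation genes, 74 had lower values and 1 fell (0 adjusted over the list alone; median -0.55, camera adjusted p = 4.6e-05, and adjusted p = 0.9 with an estimated correlation), a call lost without KO untreated A (0.13). Gata6, the transcription factor of large peritoneal macrophages, fell (log2 change -1.13, adjusted p = 0.0403), and had -0.95 in WT (adjusted p = 0.0609; 0.0438 with the letter as a block). Its call in KO was lost without KO untreated B, KO LPS A or KO LPS B. Pparg had changes of -1.23 in WT (adjusted p = 0.213) and -1.64 in KO (adjusted p = 0.127; 0.0413 with the letter as a block). Abca1 had 0.80 in KO (adjusted p = 0.128; 0.0459 with the letter as a block).

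Alternative activation genes were not called as a list in KO (1 of 17 up and 1 down; 4 and 3 adjusted over the list alone; median 0.05, mean -0.01, camera adjusted p = 0.1 in the upward direction). Arg1 fell here, from 29.83 ± 10.02 to 11.96 ± 0.67 RPKM (SD, n = 2; log2 -1.21, adjusted p = 0.0433), while Mrc1 (-1.28, adjusted p = 0.154), Retnla (-0.13, adjusted p = 0.908) and Cd36 (-0.85, adjusted p = 0.281) did not pass. The fall of Arg1 lost its call with median-ratio scaling (adjusted p = 0.112), quantile normalization (0.0655) and no filter (0.0742). It was also lost without KO untreated B (0.136), KO LPS A (0.15), KO LPS B (0.24), WT untreated A (0.0788) or WT untreated B (0.0785).

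In KO, 373 loci rose and 373 fell, and 3292 had an unadjusted p under 0.05 where chance gives 564. With the letter as a block 592 rose and 1019 fell. The count was 15 without KO LPS B, 35 without KO untreated B, 68 without KO LPS A, 376 without KO untreated A, 400 without WT untreated A, 401 without WT untreated B, 1512 without WT LPS A and 1546 without WT LPS B. Of 59 named genes called here, 57 lost their call without KO LPS B, 54 without KO untreated B, 45 without KO LPS A, 28 without KO untreated A, 15 without WT untreated A, 14 without WT untreated B, 1 without WT LPS A and 0 without WT LPS B. Slc7a2 and Mmp3 kept it throughout.

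The LPS responses of WT and KO, which share no library, were alike across loci. Their log2 changes correlated at r = 0.831 (Spearman 0.811) over 11272 loci, with a major-axis slope of 0.997 for KO on WT. Within letters the correlation was 0.718 for A and 0.729 for B, and the response of A correlated with that of B at 0.743 in WT and 0.693 in KO. Of the called loci, 248 rose and 198 fell in both genotypes, where independent lists would share 11.8 and 11.7. The lists of calls are not independent, because both tests used the same estimate of variance for a locus. Numbers for independent lists can therefore be too low. Only Arg1 was called in opposite directions, where independent lists would give 23.5 such loci. The responses of the B libraries were larger than those of the A libraries, with a standard deviation over loci of 1.03 against 0.782 in WT and 0.999 against 0.837 in KO.

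**Figure D2:**
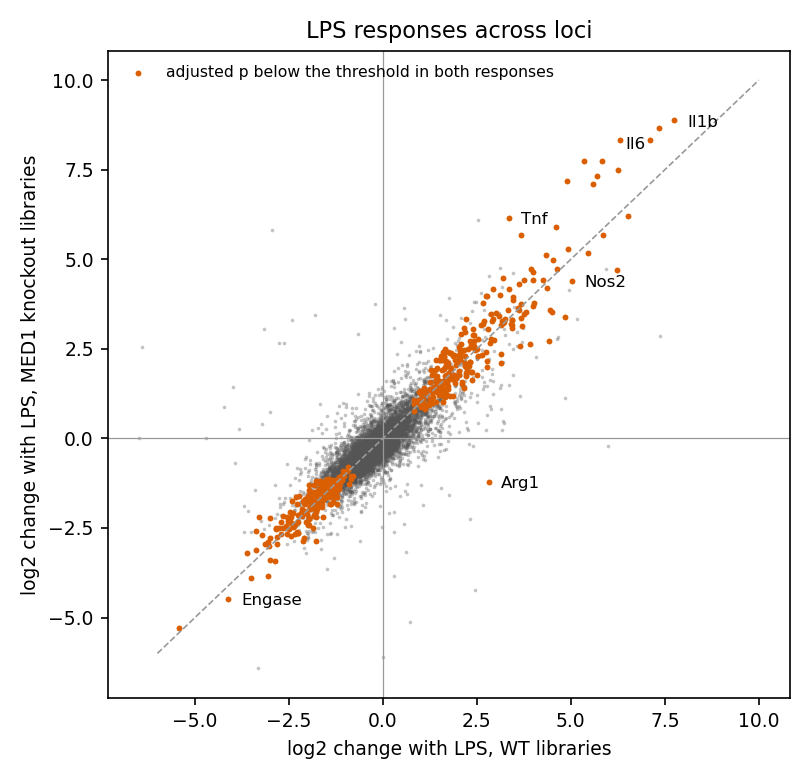
Log2 change with LPS of each locus in WT (x axis) and in KO (y axis), 1 point per locus, with loci called in both genotypes in orange, all others in grey, a dashed diagonal and 6 genes named. Points follow the diagonal (r = 0.831), and Arg1 lies apart, at 2.82 in WT and -1.21 in KO.

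Whether loss of MED1 changes resting macrophages is asked by the untreated comparison. No protein-coding gene passed in it. The 3 called loci are microRNA genes. Mir1894 was at 48.6 and 93.8 RPKM in KO untreated and Mir5133 (96.5 and 80.7) and Mir3473e (27.4 and 22.9) in WT untreated, each listed at 0 in the other 6 libraries. Limma gave adjusted p = 0.000556 for Mir1894, 5.56e-05 for Mir5133 and 0.000385 for Mir3473e, and the last was lost with a filter at 5 RPKM (0.13). The count was 5 without WT untreated A. Without small RNA loci limma called 0, and with them 94 loci had an unadjusted p under 0.05 where chance gives 564. The protein-coding genes with the smallest p, none passing (adjusted p = 1), were the tumour necrosis factor receptor Cd27 (log2 2.27), Rnf19a (1.91) and the interferon-induced Rtp4 (1.15) on the higher side and the lysozyme Lyz2 (-1.43), the cytokine Il1f9 (-1.04) and Arg1 (-0.82) on the lower.

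Several lists shifted in untreated KO, with 0 members passing singly in any of them and an estimated-correlation adjusted p of at least 0.44. Interferon-response genes were higher in 29 of 30 members (median 0.59, camera adjusted p = 7.7e-08, and adjusted p = 0.73 with an estimated correlation), a call lost without KO untreated B (0.11, median 0.17), while without KO untreated A the median was 0.91. B cell markers were higher in 13 of 13 (median 0.75, camera adjusted p = 4.5e-06, and adjusted p = 0.73 with an estimated correlation), for instance Ms4a1, which encodes CD20, at 1.05. MHC class II genes, which B cells also express, were higher in 10 of 11 (median 0.56, camera adjusted p = 0.005, and adjusted p = 0.74 with an estimated correlation). Both rested on KO untreated B: without it the medians were -0.08 (adjusted p = 0.17) and -0.10 (0.064), without KO untreated A they were 1.57 and 1.29, and MHC class II also lost its call without WT untreated A (0.052). Microbicidal and prostaglandin genes were lower in 15 of 16 (median -0.44, camera adjusted p = 1.3e-09, and adjusted p = 0.44 with an estimated correlation), with Lyz2 and the prostaglandin E synthase Ptges (-1.23) furthest, and a median of -0.17 without WT untreated B. NRF2 antioxidant genes were lower in 12 of 12 (median -0.67, camera adjusted p = 3.8e-10, and adjusted p = 0.61 with an estimated correlation), a call lost without WT untreated B (0.12, median -0.10) or KO untreated B (0.08, median -0.18). Without WT untreated A or KO untreated A the median was -1.12 or -1.03. Their mean was higher in KO by 0.33 in letter A and lower in letter B (-1.64). Glycolysis and HIF1 target genes were lower in 17 of 19 (median -0.28, camera adjusted p = 3.9e-05, and adjusted p = 0.73 with an estimated correlation), lost without WT untreated A (0.42, median -0.06) and, with a median of 0.23, without KO untreated B (0.16). Without KO untreated A it was -0.83 and without WT untreated B -0.49. With the B cell score as covariate, the medians of MHC class II (-0.05, adjusted p = 0.29) and glycolysis genes (0.14, adjusted p = 0.4) changed sign and their calls were lost.

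Shifts were also called in 7 other lists in untreated KO, 2 of which (cholesterol synthesis and sex-linked genes) are given in the closing observations. Alternative activation genes were lower in 10 of 17 (median -0.03, camera adjusted p = 0.0062, and adjusted p = 0.44 with an estimated correlation), lost with median-ratio scaling (0.069) and without WT untreated A (0.088, median -0.29) or KO untreated B (0.18, median -0.14), with medians of -0.19 without KO untreated A and -0.15 without WT untreated B. NF-kB regulators were lower in 16 of 23 (median -0.16, camera adjusted p = 0.005, and adjusted p = 0.74 with an estimated correlation), lost with median-ratio scaling (0.051), without WT untreated B (0.22) and, with a median of 0.02, without KO untreated A (0.49). Ribosomal protein genes were higher in 66 of 76 (median 0.14, camera adjusted p = 0.047, and adjusted p = 0.83 with an estimated correlation, and 0.055 with the letter as a block), lost with median-ratio scaling (0.12) and without each library but KO untreated A, with adjusted p from 0.074 without KO untreated B, where the median was -0.04, to 0.19 without WT untreated A. Oxidative phosphorylation genes were split, 37 higher and 38 lower, against a median of 0.07 over all loci (list median -0.00, mean 0.00, camera downward with adjusted p = 0.047, and adjusted p = 0.83 with an estimated correlation, and 0.055 with the letter as a block). Without KO untreated B they were higher (median 0.15, adjusted p = 0.0035), and without WT untreated A (0.4), WT LPS A (0.12) or WT LPS B (0.12) the call was lost. Mesothelial and stromal genes were lower in 4 of 4 (median -0.44, camera adjusted p = 0.0075, and adjusted p = 0.73 with an estimated correlation), lost with median-ratio scaling (0.068), without KO untreated A (0.17), KO untreated B (0.072) or, with a median of 0.33, WT untreated B (0.19). Without WT untreated A it was -1.35. Of the 12 genes of this list, 4 lay above the filter. The mean log2(RPKM + 1) of the 12 was 0.25 to 0.98 over the libraries, close to the floor. With the B cell score as covariate, alternative activation (0.241) and ribosomal protein genes (0.238) lost their calls, and oxidative phosphorylation genes were higher (0.12, adjusted p = 0.03).

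**Figure D3:**
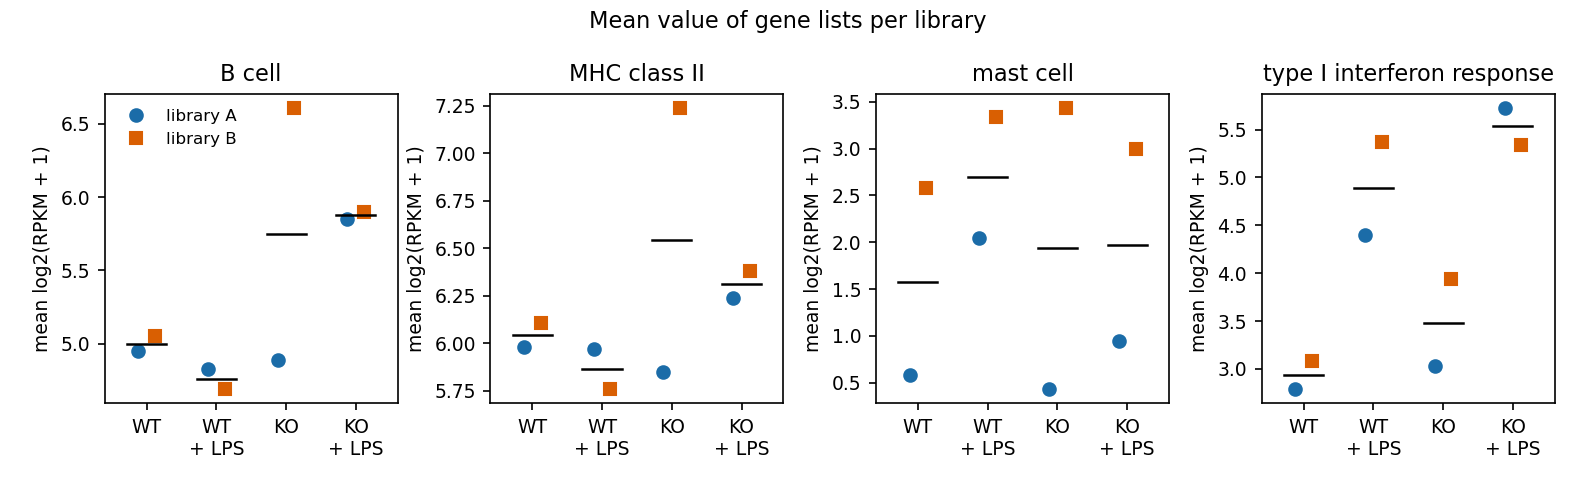
Mean log2(RPKM + 1) of the genes of 4 lists (y axis) per library in the 4 groups (x axis), with circles for libraries A, squares for libraries B and a line at the group mean. KO untreated B has the highest B cell (6.61) and MHC class II (7.24) values, and mast cell values are higher in B than in A in each group.

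The comparison of KO with WT under LPS asks whether activated macrophages differ. One gene passed, Arg1 (XLOC_001945, chromosome 10, 24635014 to 24647276, minus strand), which was 31.4 times lower in KO: 11.5 and 12.4 RPKM against 325 and 425 in WT. The log2 difference was -4.85 (SE 0.27, 95% interval -5.48 to -4.22, adjusted p = 0.00261), larger than the spread between libraries, and it missed the threshold without KO LPS A (-4.80, adjusted p = 0.0609). The count of called loci was then 0 in limma. It was 6 without WT LPS A, 3 without either WT untreated library, and 2 without WT LPS B, KO LPS B or either KO untreated library. With all libraries 498 loci had an unadjusted p under 0.05, where chance gives 564. The genes with the next smallest p did not pass. On the lower side they were the nucleotide receptor P2ry6 (-2.77, adjusted p = 0.365), the orphan receptor Gpr141 (-1.86, adjusted p = 0.365) and the chemokine Ccl6 (-1.86, adjusted p = 0.388). On the higher side they were Rasgef1b (1.52, adjusted p = 0.544), the transcription factor Mef2b (1.78, adjusted p = 0.731) and the T cell adaptor Lat (1.79, adjusted p = 0.784).

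None of the inflammatory mediators named here passed singly under LPS. Tnf was at 115 and 436 RPKM in WT and 680 and 1881 in KO, a log2 difference of 2.33 (SE 0.70, 95% interval 0.70 to 3.96, adjusted p = 0.989), and Il6 had 1.18, Il1b 0.22, Ptgs2 1.16 and Nos2 -0.66, none passing. As a list, cytokines were higher in 16 of 18 (median 0.81, camera adjusted p = 0.0014, and adjusted p = 0.78 with an estimated correlation). That shift rested on WT LPS A: without it the median was -0.48 (adjusted p = 0.034), without KO LPS B it was 0.04 (0.64), and without WT LPS B it was 1.60. Interferon-response genes were higher in 25 of 30 (median 0.54, camera adjusted p = 9.2e-09, and adjusted p = 0.68 with an estimated correlation), for instance Rsad2 (1.63) and the RNA-sensing regulator Oasl1 (1.40), with the call lost without WT LPS A (0.95, median 0.25) and medians of 0.32 without KO LPS A and 0.92 without WT LPS B. Chemokines were not called (13 of 18 higher, median 0.34, camera adjusted p = 0.68) and went opposite ways without WT LPS A (-0.41, adjusted p = 8.7e-05) and WT LPS B (1.38, 1.3e-07).

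Alternative activation genes were lower in 12 of 17 under LPS, with Arg1 passing over all loci (median -0.21, camera adjusted p = 0.0013, and adjusted p = 0.51 with an estimated correlation; fry adjusted p = 0.043). Among lists of MED1 loss and of the interaction this was the only one that fry called. The list was not tested without Arg1, so these calls are not separate from the change of Arg1. The camera call was lost without WT LPS B (0.49, median -0.06) and with the B cell score as covariate (0.271), and the median was -0.37 without WT LPS A and -0.54 without KO LPS A. Adjusted over the list alone, Arg1 and the scavenger receptor Stab1 (-1.64) were lower and the transcription factor Irf4 (1.24) higher. Microbicidal and prostaglandin genes were lower in 13 of 16 (median -0.23, camera adjusted p = 0.0074, and adjusted p = 0.68 with an estimated correlation), lost without KO LPS A (0.26, median -0.36) or WT LPS B (0.61, median -0.16), with a median of -0.51 without WT LPS A. Glycolysis and HIF1 target genes were lower in 16 of 19 (median -0.52, camera adjusted p = 9.3e-06, and adjusted p = 0.68 with an estimated correlation), with the lactate exporter Slc16a3 (-1.31), Bnip3 (-1.20) and Hif1a itself (-0.97) not passing singly. Their median was -0.16 without WT LPS A and -0.09 without KO LPS B, and with the B cell score as covariate it was 0.21 and the call was lost (adjusted p = 0.271). NRF2 antioxidant genes were higher in 10 of 12 (median 0.67, camera adjusted p = 0.0093, and adjusted p = 0.78 with an estimated correlation), lost without WT LPS A (0.86) or KO LPS B (0.091). Ribosomal protein genes were higher in 76 of 76 (median 0.26, camera adjusted p = 9.8e-08, and adjusted p = 0.78 with an estimated correlation), a call lost with the B cell score as covariate (0.439, median 0.02).

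Markers of other cells moved with genotype under LPS as well. B cell markers were higher in 13 of 13 (median 1.15, camera adjusted p = 9.2e-09, and adjusted p = 0.68 with an estimated correlation), with Ms4a1 at 1.34. MHC class II genes were higher in 9 of 11 (median 0.55, camera adjusted p = 0.067; 0.027 with the letter as a block), and were called without KO LPS A (0.013) or either KO untreated library (0.0015 each). Pan-macrophage genes were lower in 7 of 12 (median -0.35, camera adjusted p = 0.0047, and adjusted p = 0.68 with an estimated correlation), lost without WT LPS B (0.13), and with a median of -0.10 without WT LPS A. Mesothelial and stromal genes were lower in 4 of 4 above the filter, of 12 in the list. Their median was -1.63 (camera adjusted p = 4.9e-07, and adjusted p = 0.66 with an estimated correlation). All 4 passed adjusted over the list alone against 0 over all loci, with the collagen-binding Dcn at -2.12 (adjusted p = 0.784).

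Averaged over treatments, with 4 libraries against 4, Arg1 was lower in KO in 4 of 4 letter pairs (log2 -2.83, SE 0.19, 95% interval -3.28 to -2.39, adjusted p = 0.00341), and was called with each library left out in turn. In the additive model the same difference had an SE of 0.72 and was not called (adjusted p = 0.941), since that model counts the difference between the responses as spread. The other 3 calls were the microRNA genes named above, at 3.05 for Mir1894, -2.35 for Mir3473e and -3.24 for Mir5133, sizes that the pseudocount sets (4.70, -3.99 and -4.89 with 0.1, where Mir1894 and Mir3473e were not called, adjusted p = 0.065 and 0.25). Mir1894 lost its call without WT LPS B (0.0539). The count was 7 without WT untreated A, it was 1 without small RNA loci, and 472 loci had an unadjusted p under 0.05 where chance gives 564. Lyz2, which encodes lysozyme (XLOC_002297, chromosome 10, 116714390 to 116719377, minus strand), was among the most abundant transcripts and lay lower in 4 of 4 pairs. Its means were 30450 RPKM in WT and 11750 in KO, and 15280 and 4829 with LPS (log2 -1.54, SE 0.30, 95% interval -2.24 to -0.84), but it did not pass over all loci (adjusted p = 0.999). Not passing either, with the smallest p, were Lat (1.42), the interferon-induced protease Usp18 (0.95) and Rasgef1b (0.80) on the higher side and the inflammasome protein Mefv (-0.95), the phosphatase Ppm1h (-1.47) and Gpr141 (-0.90) on the lower side.

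Interferon-response genes were higher in KO in 28 of 30 members on average (median 0.53, camera adjusted p = 1.4e-11, and adjusted p = 0.46 with an estimated correlation), and their mean was higher in KO in 3 of 4 letter pairs. Without WT LPS A their median was 0.31. Oasl1 and Usp18 passed adjusted over the list alone, and 0 over all loci. B cell markers were higher in 13 of 13 (median 0.94, camera adjusted p = 3.2e-10, and adjusted p = 0.46 with an estimated correlation), 11 of them adjusted over the list alone and 0 over all loci, and in 3 of 4 pairs, with a median of 0.52 without KO untreated B. MHC class II genes were higher in 10 of 11 (median 0.56, camera adjusted p = 0.0051, and adjusted p = 0.65 with an estimated correlation), lost without WT LPS A (0.11) or KO untreated B (0.17, median 0.16), and lower with the B cell score as covariate (median -0.19, adjusted p = 0.0152). Ribosomal protein genes were higher in 72 of 76 (median 0.20, camera adjusted p = 6.2e-07, and adjusted p = 0.73 with an estimated correlation), with a median of 0.11 without KO untreated B and the call lost with the B cell score as covariate (0.918, median 0.00). Cytokines were higher in 15 of 18 (median 0.49, camera adjusted p = 0.12; 0.024 with the letter as a block), with a median of -0.21 without WT LPS A (adjusted p = 0.016). They were called upward without KO LPS A (5.2e-05), WT untreated B (0.028) or WT LPS B (1.8e-09).

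On the lower side on average were glycolysis and HIF1 target genes, in 19 of 19 members and in 4 of 4 pairs (median -0.36, camera adjusted p = 3.5e-08, and adjusted p = 0.46 with an estimated correlation). This shift is not separated from that of B cell markers: with the B cell score as covariate the median was 0.22 and the call was lost (adjusted p = 0.236). Without KO untreated B the median was -0.01, without WT untreated A -0.21, without WT LPS A or KO LPS B -0.17, and without KO untreated A -0.57. Microbicidal and prostaglandin genes were lower in 15 of 16 and in 4 of 4 pairs, Lyz2 alone passing over the list alone. Their median was -0.35 (camera adjusted p = 2.2e-07, and adjusted p = 0.43 with an estimated correlation). It was -0.19 without WT untreated B and -0.54 without WT LPS A. Lyz2 belongs to this list and to the pan-macrophage list, and camera was not run on either without it. Their calls, here and within treatments, are thus not separate from the change of Lyz2. Alternative activation genes, Arg1 among them, were lower in 12 of 17 and in 4 of 4 pairs (median -0.25, camera adjusted p = 8.7e-05, and adjusted p = 0.3 with an estimated correlation). That call was lost with the B cell score as covariate (0.195, median -0.15) and with fry (0.058), and the median was -0.15 without KO LPS B. Pan-macrophage genes were lower in 8 of 12 (median -0.22, camera adjusted p = 0.0061, and adjusted p = 0.46 with an estimated correlation), lost without KO untreated A (0.35) or WT LPS B (0.059), and with medians of -0.13 without WT LPS A and -0.09 without KO LPS B. Mesothelial and stromal genes were lower in 4 of 4 (median -1.09, camera adjusted p = 2.7e-07, and adjusted p = 0.43 with an estimated correlation), with a median of -0.65 without WT untreated B.

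The interaction asks whether the LPS response itself differs between genotypes. Arg1 rose with LPS in WT and fell in KO, and the difference between its responses was -4.03 (SE 0.38, 95% interval -4.92 to -3.14, adjusted p = 0.0284). Its direction held under each alternative, but the call was lost in 12 of 22, with adjusted p from 0.0536 to 0.246. It was lost with median-ratio scaling (0.131), quantile normalization (0.0653), no filter (0.0999) and without WT untreated A (0.0993), WT untreated B (0.16), WT LPS A (0.0679), WT LPS B (0.152), KO LPS A (0.246) or KO LPS B (0.17). The other 3 calls were Mir1894 (-6.10), Mir3473e (4.70) and Mir5133 (6.48), which with a pseudocount of 0.1 were -9.40, 7.97 and 9.79 and not called (adjusted p = 0.065, 0.25 and 0.059). Without small RNA loci limma called 0. The count of calls depended on which library was left out. With all libraries 184 loci had an unadjusted p under 0.05, where chance gives 564. Small p-values were thus rarer than chance gives, so the lack of calls does not show that the genotypes respond alike. Next, without passing (adjusted p = 1), came Glipr1 (1.52), Rasgef1b (1.43) and the scavenger receptor Colec12 (1.34) on the higher side and P2ry6 (-2.96), Ccl6 (-2.08) and Gpr141 (-1.92) on the lower.

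The list whose LPS response differed most was the NRF2 antioxidant response, higher in KO by a median of 1.34 in 11 of 12 genes (camera adjusted p = 1.8e-10, and adjusted p = 0.94 with an estimated correlation), with the quinone reductase Nqo1 (1.67) and the heme oxygenase Hmox1 (1.52) among them, none passing singly. The median was 0.73 without WT untreated B and 0.80 without KO untreated B. Within letters, the KO minus WT difference of the list mean went from 0.33 to 0.65 with LPS in A and from -1.64 to 0.45 in B. The cytokine response was larger in KO in 16 of 18 (median 1.05, camera adjusted p = 0.00017, and adjusted p = 0.94 with an estimated correlation), with Tnf at 2.81 (adjusted p = 1). That call was lost without KO LPS B (0.27, median 0.27) and, with a median of -0.20, without WT LPS A (0.29). The median was 0.66 without WT untreated B and 2.04 without WT LPS B. For the genotype effects, the untreated and LPS comparisons correlated across loci at r = 0.157.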

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

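The tests of the share of macrophages, of scaling and of B cells, and the lists without single libraries, were chosen after the results were seen, and the count of other splits before. The interaction test, which asks whether the LPS response differs between KO and WT, picked out the results of this part. Arg1 had a difference of -4.03. The microRNA genes had -6.10 (Mir1894), 4.70 (Mir3473e) and 6.48 (Mir5133), but these differences arise in untreated libraries alone, since all 3 were listed at 0 in every LPS library. Their size is set by the pseudocount: with 0.1 they were -9.40, 7.97 and 9.79, and none of them was called (adjusted p = 0.065, 0.25 and 0.059). Among lists, the median response was higher in KO for NRF2 antioxidant genes (1.34), cytokines (1.05), B cell markers (0.41), NF-kB regulators (0.27), cholesterol synthesis (0.21), oxidative phosphorylation (0.15) and ribosomal proteins (0.13). It was lower for mesothelial and stromal genes (-1.19). Mast cell markers, lower in 10 of 10 (-1.03), were called only with the letter as a block (adjusted p = 0.097, and 0.00041 with it). For the 8 called lists, camera gave adjusted p = 1.8e-10, 0.00017, 0.027, 0.031, 0.015, 0.0033, 0.0026 and 0.0027 in that order, and adjusted p = 0.94 for each with an estimated correlation.

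Of these lists, only NRF2 kept its call without each of the 8 libraries, but its median was 0.73 without WT untreated B and 0.80 without KO untreated B. Cytokines (-0.20), NF-kB regulators (-0.09) and cholesterol synthesis (-0.22) turned negative without WT LPS A, cholesterol synthesis with adjusted p = 0.015. NF-kB regulators also lost the call without KO untreated A (0.37), WT untreated B (0.3) and KO LPS B (0.9), cytokines without KO LPS B (0.27) and cholesterol synthesis without WT untreated A (0.084) and KO untreated A (0.25). Oxidative phosphorylation lost it without WT untreated A (0.05) and had medians of -0.04, -0.10 and -0.01 without KO LPS A, WT LPS B and KO untreated B. Ribosomal proteins lost it without WT LPS A (0.17) and had -0.05 without KO untreated A. B cell markers lost it without WT untreated A (0.069), WT LPS A (0.34) and KO LPS B (0.13), and had -0.46 without KO untreated A (0.05). Mesothelial genes had a median of -2.09 without WT untreated B, and lost the call without WT untreated A (0.22, median -0.28), KO untreated A (0.091) and WT LPS B (0.33).

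Arg1 under LPS lay 4.85 log2 units below WT in KO, a pattern for which a lower share of macrophages and scaling were tested. A lower share of macrophages would lower their other markers by about as much, but 12 pan-macrophage genes had a median of -0.34 (SD 0.75). Under the scaling that left it smallest, the Arg1 difference was -4.76 (SE 0.26). Both tests argue against these explanations, and loss of MED1 stays open as a hypothesis, with Arg1 lower in KO in 4 of 4 letter pairs. Other changes in the composition of the samples were not tested and stay open. The sex of the animals also stays open, untested: in WT LPS A and B and KO LPS A and B, Xist (12.9, 41.1, 61.8 and 51.3 RPKM) parted the genotypes as Arg1 did (325, 425, 11.5 and 12.4), and Ddx3y (22.3, 5.63, 3.62 and 11.4) did not.

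The 4 loci called for MED1 loss averaged over treatments do not exclude chance by their number. Of 34 splits of the 8 libraries into 4 and 4, 12, the genotype split included, gave at least as many. That number cannot decide the matter, since some other splits hold differences of their own, among them the interaction (4 calls). It also takes no account of the size of a change, such as that of Arg1. The highest other count was 102, from the split of A against B, which points to a structure of the samples that follows the letters. Among the 8 splits that part all 4 letter pairs, 7, the genotype split included, gave as many and the highest other gave 6. With the letter as a block the genotype split gave 4.

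B cell markers were higher in KO, and their mean log2 value was 5.81 in KO and 4.88 in WT (exact permutation p = 0.086 over 70 splits), with 3 of 4 KO libraries above all WT libraries. If a lower share of macrophages were the cause, markers of other cells would rise alike. Under LPS, mesothelial and stromal genes (4 tested of 12) had a median of -1.63 against 1.15 for B cell markers (SD 0.26). Without LPS, T and NK cell (0.59), eosinophil (0.52, 2 genes tested) and mast cell markers (0.42) were higher in KO beside B cell markers (0.75). Mesothelial and stromal genes (-0.44) and neutrophil markers (-0.22) were lower. The rises of T and NK cell, mast cell and B cell markers rested on KO untreated B. Without it their medians were -0.43, -0.76 and -0.08. Without WT untreated B the mesothelial and stromal median was 0.33. Other cells thus moved both ways. KO untreated B, with the highest B cell mean (6.61), also had the highest pan-macrophage mean of the 8 libraries (8.31). Its B cell value thus did not come with lower pan-macrophage values. In the other letter pairs the pan-macrophage mean was lower in KO (-0.27 untreated A, -0.42 LPS A and -0.33 LPS B). Together these values do not decide on the share of macrophages. A candidate explanation is more B cells in some libraries, since MHC class II genes, none of them in the B cell list, followed the B cell mean over the 8 libraries (r = 0.94, exact permutation p = 9.9e-05; without KO untreated B and KO LPS B r = 0.87, p = 0.0042). The most abundant B cell genes reached 514 RPKM (Ms4a1) and 496 RPKM (Cd79b) in KO untreated B, against 113 and 179 in WT untreated B. Whether the share of B cells follows genotype or the preparation stays open, and no sort or gate is named in the labels.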

How the results depend on the processing

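Small RNA loci left out and the B cell and mast cell scores were tests chosen after the results were seen. For gene lists, so were all settings but median-ratio scaling, the letter as a block, the estimated correlation and fry. The other tests were chosen before. With WT LPS calls at 711, 270 were made with no filter, 1818 with the letter as a block and 130 with the compared libraries alone. With 746 in KO, the same settings gave 262, 1611 and 462, and the mast cell score 1332. The 3 calls for MED1 loss without LPS were 0 without small RNA loci. The 1 call with LPS was 2 with no filter and 4 with the compared libraries alone. The 4 averaged calls were 2 with a pseudocount of 0.1, 2 with a filter at 5 RPKM, 1 without small RNA loci and 0 with the additive model. The 4 interaction calls were 0 under the first 3 of these settings. The correlation of LPS responses, 0.831, was 0.794 and 0.82 with pseudocounts of 0.1 and 0.5, 0.811 with no filter and 0.876 without small RNA loci. With each library left out in turn, with the lone sample of a group assumed to vary like the other groups, counts ranged from 9 to 2242 (LPS in WT), 15 to 1546 (LPS in KO), 3 to 5 (MED1 loss untreated), 0 to 6 (LPS), 4 to 7 (averaged) and 1 to 7 (interaction), and the correlation from 0.706 to 0.835. The cause was not tested. Of 16786 values for 764 gene results, 16044 stayed the same, 521 were weaker, 221 stronger and 0 reversed, where reversed means a change of sign with a call before or after. Those that stayed the same include 395 that changed sign without a call. Of 4320 values for 180 list results, 3807 stayed the same, 281 were weaker, 176 stronger and 56 turned in direction with a call before or after, and the first number includes 293 that changed sign without a call. Of 68 list calls, 68 were lost with an estimated correlation, 56 with fry and 17 with median-ratio scaling. Fry called 0 lists for MED1 loss untreated (lowest adjusted p = 0.99), averaged (0.058) and the interaction (0.65). Of the 68, 49 had a median that moved over 1.5 times or changed sign without at least 1 library.

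With the B cell score as covariate, the direction that camera gave turned for the lists below, whose medians are given in the order untreated, LPS and averaged where 3 are given. They were -0.052, -0.39 and -0.194 for MHC class II, 0.142, 0.211 and 0.219 for glycolysis, 0.299, 0.284 (from 0.02, so that the sign of the median stayed) and 0.228 for immediate early genes and -0.335, -0.871 and -0.664 for T and NK cells. Untreated alone they were 0.122 for oxidative phosphorylation, -0.011 for ribosomal proteins, -0.002 for B cells (fixed by the score, which is the mean of that list) and -0.655 for mast cells, and averaged 0.382 for NRF2 and 0.248 for sex-linked genes. With the mast cell score, LPS in WT gave -0.87 for T and NK cells (from -0.16) and -0.407 for mast cells. With each library left out, the medians of lists whose camera direction turned ranged as follows. Under LPS, MED1 loss gave -0.485 to 1.602 for cytokines, -0.415 to 1.383 for chemokines, -0.227 to 0.297 for NF-kB regulators, -0.399 to 0.464 for cholesterol synthesis and -0.507 to -0.157 for microbicidal genes, whose median stayed negative while camera's direction turned without WT LPS B (adjusted p = 0.612). Averaged, it gave -0.213 to 0.778 for cytokines, -0.267 to 0.541 for chemokines, -0.252 to 0.098 for NF-kB regulators, -0.198 to 0.167 for cholesterol synthesis, -0.036 to 0.17 for oxidative phosphorylation and -0.438 to 0.172 for large peritoneal macrophages. Untreated, it gave -0.099 to 1.287 for MHC class II, -0.833 to 0.232 for glycolysis, -0.189 to 0.146 for oxidative phosphorylation, -0.036 to 0.314 for ribosomal proteins, -0.77 to 0.733 for large peritoneal macrophages, -0.084 to 1.572 for B cells, -0.433 to 1.434 for T and NK cells, -0.762 to 1.388 for mast cells and -1.348 to 0.327 for mesothelial genes. The interaction gave -0.202 to 2.041 for cytokines, -0.07 to 1.139 for chemokines, -0.091 to 0.517 for NF-kB regulators, -0.226 to 0.642 for interferon-response genes, -0.217 to 0.62 for cholesterol synthesis, -0.732 to 0.67 for MHC class II, -0.585 to 0.312 for glycolysis, -0.097 to 0.393 for oxidative phosphorylation, -0.786 to 0.471 for large peritoneal macrophages, -0.459 to 1.235 for B cells and -0.872 to 0.924 for T and NK cells. LPS in WT gave -0.393 to 0.547 for cholesterol synthesis and LPS in KO -0.854 to 0.701 for MHC class II. Depth limits what can be seen at low levels, where 1 read per kb stands for up to 0.141 RPKM.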

Other observations

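The tests of Lyz2 and of the microRNA genes, and the lists without single libraries, were chosen after the results were seen. Several lists not described so far moved with LPS in WT by camera. Immediate early and heat shock genes had a median of 0.08 in WT (1 of 14 rose, adjusted p = 0.018, and 0.52 with an estimated correlation) and 0.06 in KO (2 rose, adjusted p = 0.016, and 0.44 with an estimated correlation), including Ier3 (2.16 in WT, 3.09 in KO). With the letter as a block these were 0.073 and 0.068, with median-ratio scaling 0.098 and 0.072, and they were lost without WT untreated B (0.15) or WT LPS B (0.12) in WT and KO untreated B (0.4) in KO. Glycolysis and HIF1 targets had a median of -0.07 but a mean of 0.24 in WT, and camera called them upward (adjusted p = 0.036, and 0.87 with an estimated correlation), with Hif1a rising by 1.92. That call was lost with the letter as a block (0.073), with median-ratio scaling (0.12) and without WT LPS A (median -0.25) or WT untreated B. The WT median was 0.475 without WT untreated A and 0.344 without WT LPS B. In KO the median was -0.26 (adjusted p = 0.23), and 0.33 without KO untreated A (0.00063).

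Markers of other cells were called in WT with LPS as well. Mast cell markers had a median of 0.51 (adjusted p = 0.023, and 0.87 with an estimated correlation), Hdc rising by 4.65. This list call was lost without WT untreated A (median -0.25) or WT LPS B (0.32), and the median was 1.35 without WT LPS A and 1.63 without WT untreated B. Neutrophil markers had 0.49 (adjusted p = 0.039, and 0.75 with an estimated correlation), lost without WT untreated A (median -0.01), WT LPS A (0.26) or WT LPS B. Without WT untreated B the neutrophil median was 0.999. Mesothelial and stromal genes had 0.79 (adjusted p = 0.023, and 0.72 with an estimated correlation), lost without WT untreated A (median -0.12) or WT LPS B, and with a median of 1.69 without WT untreated B. Among them Dcn rose by 1.72, a call lost without WT untreated A, WT untreated B or WT LPS B. All 3 list calls were lost with median-ratio scaling (0.22, 0.2 and 0.12). In KO these lists had -0.19, 0.02 and -0.31 and were not called.

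Genes of cholesterol synthesis did not move as 1 list with LPS (median 0.02 and mean -0.15 in WT, adjusted p = 0.83, and 0.25 in KO, adjusted p = 0.1), although the last enzyme of the pathway, Dhcr7, fell by 1.89 in WT and by 1.67 in KO. In WT the list was at 0.55 without WT LPS A (0.00026) and -0.39 without WT LPS B (0.00014). In untreated KO the list was lower in 17 of 21 genes than in WT (median -0.16, adjusted p = 9e-05, and 0.73 with an estimated correlation), lost without KO untreated A (0.17).

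Mediator subunits other than Med1 had medians of -0.07 with LPS in WT (adjusted p = 0.73) and -0.19 in KO (adjusted p = 0.98), each positive with median-ratio scaling (0.17 and 0.07). Nuclear receptors and coactivators had -0.16 and -0.44, with the retinoid receptor Rxra falling by 1.21 in KO. LXR targets in KO had -0.61, scavenger and efferocytosis receptors -0.57 in WT and -1.16 in KO, with the oxidized LDL receptor Olr1 rising by 2.81 and 3.07, and MHC class II genes -0.05 and -0.11. NRF2 genes in WT had 0.28 (adjusted p = 0.086), and 0.028 without WT LPS A and 0.00018 without WT untreated B. Cell cycle genes had -0.26 and -0.38, while Mki67 rose by 3.59 in KO. Ribosomal proteins in KO had -0.25 (adjusted p = 0.46), and 0.0052 without KO untreated A.

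Large peritoneal macrophage genes had medians of 0.03 with LPS in WT and -0.71 in KO, pan-macrophage genes -0.33 and -0.69, with the Fc receptor Fcgr1 falling by 2.49 in KO, and small peritoneal macrophage and dendritic cell genes -0.35 and 0.42. B cell markers had -0.23 and 0.24, T and NK cell markers -0.16 and -0.14, eosinophil markers -0.32 and -0.35, and sex-linked genes -0.37 and 0.30. None of these was called with all libraries. Erythroid genes lay below the filter and were not tested, but Hbb-b1 was at 45.9 RPKM in WT untreated B and listed at 0 in the other 7 libraries.

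Averaged over treatments, large peritoneal macrophage genes were lower in KO in 13 of 18 (median -0.14, adjusted p = 0.029, and 0.75 with an estimated correlation) and neutrophil markers in 5 of 5 (median -0.24, adjusted p = 0.029, and 0.62 with an estimated correlation). The neutrophil median was -0.92 without KO untreated B, -0.84 without WT untreated A and -0.07 without WT untreated B. Both calls were lost with median-ratio scaling (0.13 each). The first was lost without KO untreated A (0.45, median 0.17), KO LPS A (0.12), WT untreated B (0.073) and WT LPS B (0.48), the second without KO untreated A (0.45), KO LPS A (0.2), WT untreated B (0.48) and WT LPS B (0.24). T and NK cell markers had a median of 0.52 (adjusted p = 0.066, and 0.00093 with the letter as a block). Under LPS, mast cell markers in KO had -0.70 (adjusted p = 0.088, and 0.002 with the letter as a block). The block also gave calls for T and NK cell markers untreated (0.59, adjusted p = 0.13, and 0.0017 with it) and under LPS (0.42, 0.17 and 0.02). Under LPS it did so for oxidative phosphorylation (0.12, 0.074 and 0.019), large peritoneal macrophage genes (-0.13, 0.067 and 0.0093) and neutrophil markers (-0.47, 0.074 and 0.024), and averaged for scavenger receptors (-0.06, 0.075 and 0.039). With an estimated correlation and no block, camera called no list for MED1 loss (lowest adjusted p = 0.44 untreated, 0.51 under LPS and 0.3 averaged).

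Sex-linked genes followed genotype in part. Xist was higher in KO in 4 of 4 letter pairs, and the Y-linked Ddx3y, Eif2s3y and Kdm5d were lower in 3 of 4. The list was lower in untreated KO in 4 of 5 (median -1.63, adjusted p = 0.0013, and 0.61 with an estimated correlation) and averaged (median -1.16, adjusted p = 0.017, and 0.46 with an estimated correlation). The first call was lost without KO untreated B (median -0.37) and with the B cell score as covariate (0.241), and its median was -2.69 without KO untreated A. The averaged call was lost with median-ratio scaling (0.12) and without KO LPS A, WT LPS B or KO untreated B (median -0.56), and its median was -0.73 without WT LPS A. Ddx3y and Eif2s3y were listed at 0 in KO untreated B, where Xist was at 96.5 RPKM. The other 7 libraries had both Xist (9.28 to 61.8) and Ddx3y (3.62 to 22.3). These values point to cells of both sexes in those 7 libraries, and so argue against a single animal in each of them. The sex of the animals is not given in the sources used here. The share of each sex thus stays open, untested, beside each KO minus WT difference, Arg1 under LPS included.

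The microRNA genes called for MED1 loss had values close to the ratio that equal numbers of reads in both libraries would give: 0.836 against 0.835 for Mir5133 and Mir3473e in WT untreated B over A, and 1.93 against 1.90 for Mir1894 in KO untreated. Mir1894 lies inside the protein-coding gene Ppp1r10 on the same strand, and reads of the 2 transcripts were not told apart here. Mir5133 and Mir3473e were not found in the annotation used.

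Lyz2 was lower in KO in 4 of 4 letter pairs, by -1.54 on the log2 scale averaged over treatments (SE 0.30). The other 11 pan-macrophage genes had a median of -0.16 (SD 0.4), which argues against a lower share of macrophages. A candidate explanation is a Cre gene placed in 1 copy of Lyz2, which would lower Lyz2 by up to 1 log2 unit, inside its interval of -2.24 to -0.84, and leave its neighbour Lyz1 unchanged (0.25). The labels do not name the Cre driver, and the gene did not pass over all loci (adjusted p = 0.999), so this is a hypothesis.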
